A study of Oryza sativa with 239 samples.

How the data were processed

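Messenger RNA was measured by strand-specific RNA sequencing in leaves of rice (*Oryza sativa*) grown in a chamber, in pots with automatic irrigation. The set held 40 cultivars and lines. Most carried numbers of the World Rice Core collection (WRC), a small set of landraces and varieties kept to represent the diversity of cultivated rice. The others were IR64, Koshihikari, KP and Dro1-NIL. KP is not spelled out in the labels and is read here as Kinandang Patong, the upland variety that gave DRO1, a locus of chromosome 9 for root growth angle; Dro1-NIL is read as the line that carries this locus in the background of IR64. The sampled tissue was the youngest fully expanded leaf with the next older one, taken on day 5 of the treatment. Plants were either irrigated throughout (control) or drained (drought), and each cultivar had 3 replicates per treatment, except Dro1-NIL with 2 drought replicates. Single seedlings were raised in their own pots, but the labels do not say outright that each library came from 1 plant or that plants were grown at the same time. The series' design note and the sample labels call the treatment moderate drought with harvest on day 5, whereas the treatment protocol describes a severe drought followed by rewatering. The sample labels were followed here, so the severity of the treatment is stated only as far as they give it.

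The deposited table held raw read counts per gene model for 55986 identifiers, 1 column per library, with whole numbers and column sums that differed between libraries. Per the submitters' processing notes, STAR and featureCounts 2.0.0 were used with the genome build IRGSP-1.0. The sources used here do not give the annotation release, the strand setting, the treatment of reads with several positions or any filter, and the identifiers have the form of the MSU gene models. The columns were joined to the labels by library name, and 0 columns were left unmatched. No table that pairs these identifiers with gene symbols, functions or coordinates was at hand: 1 row of the reference at hand held an identifier of the table. Genes are therefore given by identifier, with the chromosome read from the identifier itself, without start or end. For the same reason the gene lists fixed before the data were examined, on drought, photosynthesis, infection, cell division and the circadian clock among others, matched 0 genes and were not tested. The cell types and the harvest time behind a change could not be examined either.

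Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr with a minimum count of 10, which left 28297, and library sizes were scaled by TMM. A quasi-likelihood negative binomial model was fitted with a trended dispersion estimated on 2000 genes spread over the range of abundance and interpolated to the rest. The fits and tests followed edgeR's glmQLFit and glmQLFTest in a faster arrangement. It was checked against glmQLFTest on 300 genes, where p differed by at most 2.89e-11 within 1 cultivar and 0.000487 for a difference of responses. Adjusted p values are Benjamini-Hochberg values over the tested genes, and the threshold was 0.05. A gene was called changed when it also differed by a fold of at least 2. CPM values (read counts relative to a common library size) were scaled by the same library sizes. Values are means with the SD between replicates or between cultivars, as stated.

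The comparisons were fixed before the data were examined. Drought was compared with control over the 40 cultivars with cultivar as a term. Each cultivar's own response was tested in a model with 1 mean per cultivar and treatment, in which the spread was shared by the groups. The difference of responses among cultivars was tested with the interaction contrasts together. Dro1-NIL was compared with IR64 under control, and the difference of their drought responses was tested itself. For the prediction of treatment, each cultivar in turn was left out. The 10 genes with the largest mean difference between treatments relative to its SD over the other cultivars, at a mean of at least 5 CPM, were combined into a score on log2 CPM with a prior count of 2. A score of 0 stood at the control mean of the training cultivars and 1 at their drought mean. Libraries of the left-out cultivar were assigned by the midpoint. Percentages of libraries carry Wilson intervals at 95%, and 100 swaps of the treatment labels within cultivars gave the background. The share of the score's variance among cultivars was tested with 100000 permutations of the cultivar labels, one-sided. Other permutation tests used 10000 shuffles, and Python 3.11.15 with scipy 1.17.1 ran these parts.

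Genes to name were chosen by a rule fixed before the data were examined. Because no reference paired identifiers with names, it allowed at most 2 identifiers that rose and 2 that fell for a comparison, taken by the largest log2 fold change. Over the 40 cultivars they also needed a mean of at least 5 CPM and the same direction in at least 36 cultivars. Among single cultivars, those with the most and the fewest called genes were named. Identifiers named outside this rule are marked as chosen after their values were seen. The rule also named the gene DRO1 by its RAP identifier, which could not be matched to the table, so no value is given for it.

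The comparisons were tested on simulated data with the depth and gene levels of these libraries and the trended dispersion alone. In each, 100 genes were changed by a fold of 3 and 100 by a fold of 8. Over the 40 cultivars 99 and 100 of them were recovered, with 1 other gene called. Within WRC09, with 3 libraries a side, 53 and 67 were recovered, with 7 others. Between Dro1-NIL and IR64 it was 60 and 74, with 3 others. For this pair the simulation was revised after a first run was seen. The first run kept each line's own gene levels, so that genes already different between the lines were called and counted as others, in far larger number, and the second gave both lines 1 common level. Changes in WRC09 alone were recovered by the interaction test for 6 and 47 genes, with 0 others, so that a gene differing in 1 cultivar is often missed. A change in Dro1-NIL control leaves was recovered as a difference of responses for 19 and 62 genes, with 4 others. Spread particular to single genes or to whole libraries was not simulated. Real libraries of WRC100 with exchanged treatment labels gave up to 1779 genes, so these simulated figures can be too favourable.

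The alternatives fixed before the data were examined were other size factors (RLE), other filters on low counts, leaving out each replicate number, each replicate number alone, replicate number as a block, sums per cultivar with edgeR and DESeq2 1.42.0, each cultivar alone, other fold minimums, and other numbers of genes and prior counts for the score. Added after seeing the data were libraries of at least 1 M reads only, WRC47 drought replicate 3 left out, 3 libraries that lay between 2 cultivars left out, and 1 or 2 cultivars left out. The cultivar left out alone, WRC09, was the one with the most called genes, and its control and drought plants differed in cultivar-specific genes. Where leaving out a replicate number left a group with 1 library, that library was taken to vary like those of the other groups. Intervals and limits from counts cover counting error only, since reads were counted without molecular identifiers and PCR copies are not independent molecules. No library was left out of the values in the report unless stated.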

Results

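Leaf transcriptomes were compared between irrigated and drained plants of 40 rice cultivars and lines, to find genes from which the level of drought stress perceived by a plant can be predicted. Control libraries held 5.99 to 37.4 M (mega) assigned reads, with a median of 14.8 M, and drought libraries had a median of 17 M. Drought replicates numbered 3 were shallower, with a median of 6.57 M against 21.6 M for replicates numbered 1. The drop began within drought replicates numbered 2. There, library numbers 72 to 80 held 0.237 to 8.77 M and the lower numbers 10.1 to 36.6 M. Control libraries of the same numbers held 5.99 to 17.7 M and 6.51 to 29.3 M. Control and drought libraries were named in separate series, C and D. A difference between the series cannot be told apart from drought. Of the drought libraries, 4 held under 1 M reads. These were WRC47 replicate 3 with 362 reads, WRC02 replicate 2 with 236927, WRC13 replicate 1 with 248195 and WRC28 replicate 3 with 386011. The scaling factor of the first was 20.6, whereas those of all other libraries lay between 0.804 and 1.31.

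Cultivar-specific genes were used to check the labels. The 1500 genes that differed most between cultivars, relative to within them, were chosen with these same labels, which favours the own label. Over these genes, every library except WRC47 drought replicate 3 correlated best with the other libraries of its own cultivar. For WRC09 libraries the median correlation with their own cultivar was 0.731 to 0.747, and at most 0.455 with another cultivar. The most similar profiles were those of Dro1-NIL and IR64 (r = 0.975 across genes), Koshihikari and WRC01 (0.915) and WRC05 and WRC06 (0.785); genes are not independent replicates. Although nearest to their own label, 3 libraries lay midway between 2 cultivars. In WRC16 control replicate 3 and drought replicate 2, the 232 genes expressed in only one of WRC15 and WRC16 stood at a median of 50.7% and 53.2% of the way from the WRC16 level to the WRC15 level. In WRC35 control replicate 3, 196 such genes stood at 51.1% of the way to WRC36. Genes of the other cultivar and genes of the own cultivar had medians of 49.4% and 51.6% in the WRC16 control library, 54.4% and 51.8% in the WRC16 drought library and 57% and 47.6% in the WRC35 library. Against the other libraries of its own label, no other library of at least 1 M reads came near. The next highest level of genes foreign to a cultivar was a median of 3.00% of their level at home, in WRC57 control replicate 3.

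**Figure D1:**
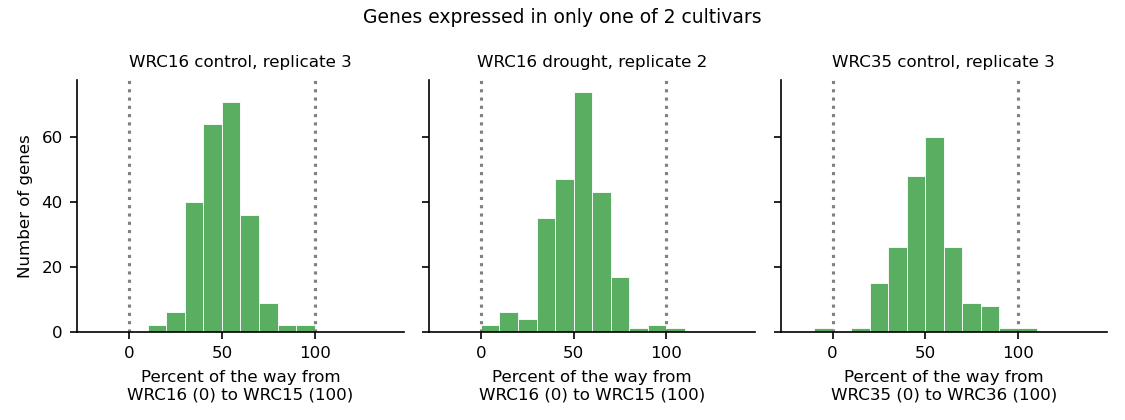
Histograms of the position of single genes in the 3 libraries, as percent of the way from the level of the labelled cultivar (0) to that of the other cultivar (100), for genes expressed in only one of the 2 cultivars; the vertical axis counts genes and positions beyond the axis are drawn at its ends. The genes form 1 group around the middle, with medians of 50.7%, 53.2% and 51.1%, and at most 2.16% of them lie near an end.

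In WRC09 the control and drought plants differed from each other in cultivar-specific genes. Over 1500 genes chosen in the other 39 cultivars, its control and drought profiles correlated at 0.451, against 0.866 in WRC05 and at least 0.987 in each of the rest. Its libraries of the same treatment correlated at a median of 0.986. Other cultivars lay about as near, with WRC18 at 0.446 to the control profile and WRC03 at 0.433 to the drought profile. In WRC09, 110 genes on 12 chromosomes had at least 5 CPM in every library of one treatment and 0 reads in the other, 51 of them read in control and 59 in drought. None of the other 39 cultivars had such a gene. LOC_Os02g40240 on chromosome 2 stood at 197 ± 20.7 CPM in control leaves, at least 2770-fold higher than the limit of 3 reads over the drought libraries. LOC_Os11g37759 on chromosome 11 stood at 166 ± 13.5 CPM in drought leaves, at least 2520-fold higher than that limit in control (SD, n = 3; both chosen after their values were seen). Of the 110 genes, 95.5% had 0 reads in every library of at least 1 other cultivar, against 3.65% of the 13824 genes with at least 5 CPM in every library of a WRC09 treatment. Values for the drought response of WRC09 below compare these 2 sets of plants. WRC05 differed in another way: its libraries of the same treatment correlated at a median of 0.775, against at least 0.974 in the other cultivars, and it had 0 genes read in only one treatment.

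Over the 40 cultivars 375 genes differed between drought and control by a fold of at least 2, with 153 higher and 222 lower in drought. LOC_Os03g54130, on chromosome 3, rose from 12.3 to 48.5 CPM (SD 13.4 and 49.4 between cultivars, n = 40), with a log2 fold change of 1.98 (SE 0.19) and the same direction in 38 cultivars. LOC_Os01g64910, on chromosome 1, rose from 3.40 to 10.5 CPM in the mean, by 1.71 on the log2 scale (SE 0.15), in 39 cultivars. LOC_Os02g14440, on chromosome 2, had a log2 fold change of -2.41 (SE 0.19), from 20.3 to 4.23 CPM, and was lower in 37 cultivars. LOC_Os10g18150, on chromosome 10, had a log2 fold change of -2.36 (SE 0.32), from 9.00 to 1.80 CPM, and was lower in 36. Their adjusted p values from edgeR lay between 2.1e-24 and 1.2e-10. These and the SE take single libraries as the unit. With counts summed per cultivar, where the cultivar is the unit, the adjusted p values from edgeR lay between 2.8e-10 and 3.5e-06.

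Most of the shared response was of modest size. The median log2 fold change was 1.22 among the genes called higher and -1.20 among those called lower, and 29 genes changed by a fold of at least 4, of which 11 were higher. Of the 375 genes, 125 moved the same way in at least 36 cultivars and 6 in all 40. The median gene moved with the call in 32 cultivars. Many were weakly expressed: 189 had a mean under 1 CPM and 123 a mean of at least 5 CPM. No chromosome passed the test for holding more or fewer of the genes called higher or lower than its share of the tested genes (Fisher's exact test, lowest adjusted p = 0.24 over 24 tests). The lowest p was that of chromosome 8, with 1.96% of the genes called higher against 7.01% of those tested. Without the fold minimum, 12567 genes passed at adjusted p under 0.05, with 6152 higher and 6415 lower. The median log2 fold change of all tested genes was -0.00136.

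The balance of directions among the called genes depended on the scaling. With RLE size factors 382 genes were called, 194 higher and 188 lower, 341 of them shared with the 375, and the median gene shifted by 0.0567. Within replicate numbers taken alone, the counts were 424, 473 and 579. Of these, 259, 168 and 163 were higher.

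The responses of single cultivars differed widely in the number of genes that passed the same threshold. WRC09, whose control and drought plants differed in cultivar-specific genes, had 3141 called genes (1541 higher and 1600 lower). All 110 genes read in only one of its treatments were among them. WRC24 had 1503 (748 and 755) and KP had 453 (229 and 224). At the other end, 8 cultivars had 0 genes called by edgeR in the shared model (WRC13, WRC18, WRC19, WRC21, WRC28, WRC33, WRC37 and WRC48, of which WRC37 had 1210 without replicate number 2). They had between 923 and 2622 genes with an unadjusted p under 0.05, where evenly spread p values would give 1415, and 4 of the 8 lay below that number. In those 4 the p values ran large, so such counts do not show that no gene changed. The median cultivar had 11.5 called genes, but 0 to 1 without one replicate number, and 0.5 in edgeR and 111.5 in DESeq2 with each cultivar fitted alone. In WRC02, WRC15 and WRC35 the called genes were mostly lower, at 408 of 442, 319 of 401 and 228 of 236. Over all cultivars, 5124 genes were called in at least 1, and 2860 when WRC09 was not counted. No gene was called in the same direction in more than 8 cultivars, or 7 without WRC09. There were 148 genes called higher in one cultivar and lower in another, and 31 without WRC09.

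**Figure D2:**
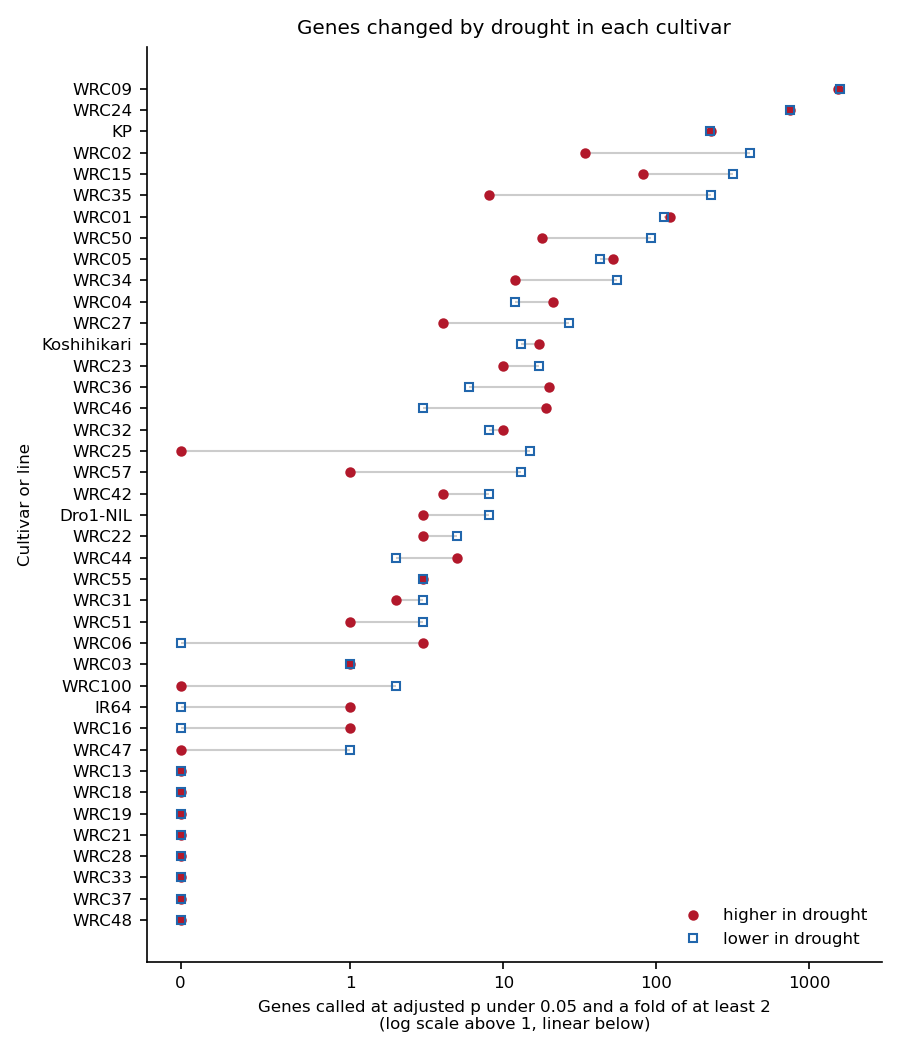
Number of genes called higher (filled circles) and lower (open squares) in drought for each of the 40 cultivars and lines, on a horizontal axis that is logarithmic above 1 and linear below. WRC09, whose control and drought plants differed in cultivar-specific genes, and WRC24 have the most genes, with 3141 and 1503, and 8 cultivars have 0; WRC24 ranks 5 without replicate number 2.

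The genes of WRC09, WRC24 and KP moved to different degrees with those of the rest. Of the called genes, 97.6% in WRC24 (1467 of 1503) and 95.8% in KP (434 of 453) had the sign of the mean response of the other 39 cultivars, against 72.6% in WRC09 (2279 of 3141). WRC09 and WRC24 shared 619 called genes, 592 of them in the same direction, where 167 are shared by lists drawn independently. Of the 375 genes called over the 40 cultivars, 153 were among those of WRC09 and 160 among those of WRC24, and 134 were called in no single cultivar.

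The counts of single cultivars were sensitive to single libraries and to the model. With treatment labels exchanged among the libraries of a cultivar, WRC100 gave up to 1779 genes, against 2 with its real labels. Without one of the replicate numbers the counts ran from 0 to 1046 in WRC02, 0 to 256 in WRC15, 1 to 198 in WRC35 and 13 to 63 in KP. Without replicate number 2, WRC37 had 1210 genes in place of 0, WRC06 had 563 in place of 3 and WRC16 had 278 in place of 1, whereas WRC24 had 379 and ranked 5. Fitted alone with edgeR, WRC24 had 495 genes and also ranked 5. In WRC35 the 236 genes fell to 1 when its control replicate 3, the library midway to WRC36, was left out together with the WRC16 libraries midway to WRC15. In WRC02, whose drought replicate 2 held 236927 reads, 340 genes in place of 442 were counted with libraries of at least 1 M reads only. Fitted alone with DESeq2, the cultivars with 0 genes in the shared model had between 0 (WRC37) and 177 (WRC33), and fitted alone with edgeR between 0 and 14.

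The shared response differed in size between cultivars. Its size was taken as the slope of a cultivar's log2 changes on the mean change of the other 39, over the 500 genes with the most uniform change in those others, without the 4 shallow libraries. The slope was above 0 in all 40 cultivars. It was highest in WRC24 at 2.51 ± 0.65, followed by WRC09 at 1.72 ± 0.51 and WRC15 at 1.69 ± 0.61, and lowest in WRC44 at 0.18 ± 0.77 and WRC51 at 0.15 ± 0.52 (SD, n = 3 differences between libraries of the same replicate number). IR64 stood at 0.93 ± 0.21 and Koshihikari at 1.32 ± 0.27. WRC18, with 0 called genes, had a slope of 1.34 ± 0.24, near that of KP at 1.35 ± 0.18 with 453 (13 to 63 without one replicate number). This measure was chosen after the data were seen.

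**Figure D3:**
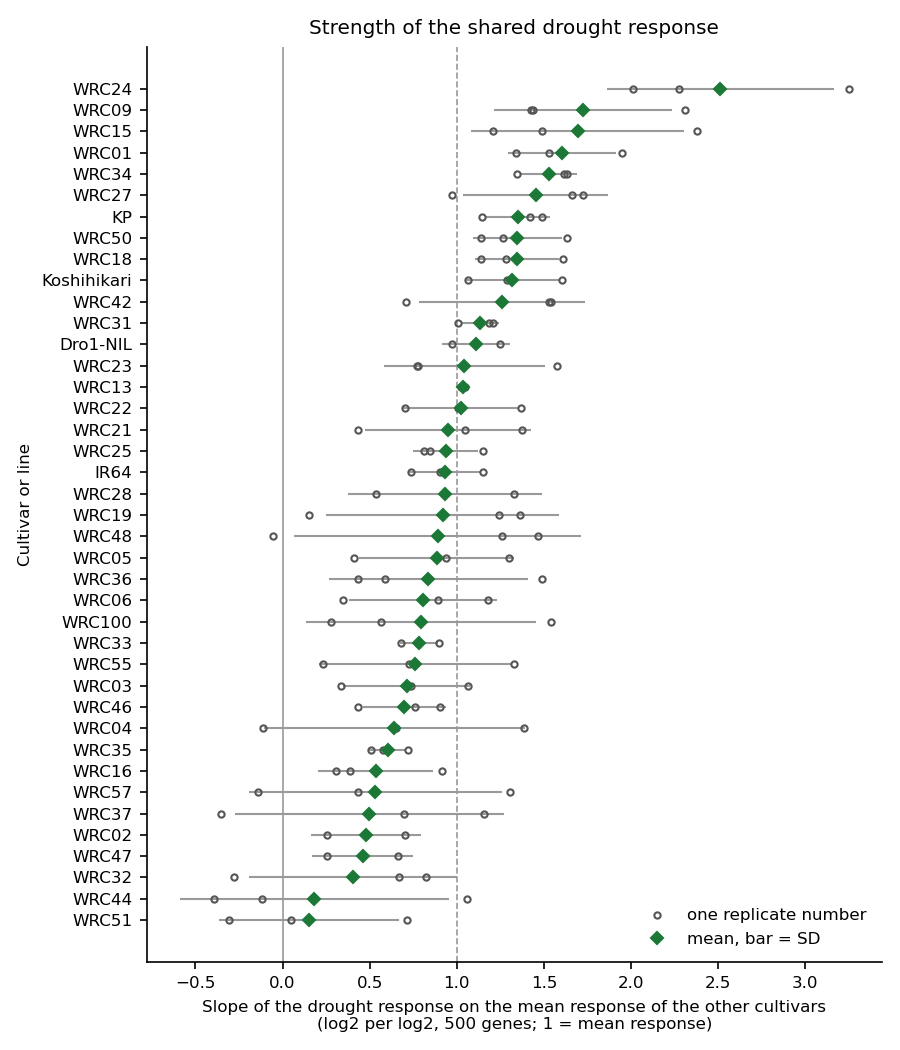
Slope of each cultivar's drought response on the mean response of the other cultivars over 500 genes (horizontal axis, log2 per log2); open circles are differences between libraries of 1 replicate number, diamonds their mean and bars the SD. The means run from 0.15 in WRC51 to 2.51 in WRC24, and the dashed line at 1 marks the mean response.

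Cultivars differed in their response at 1095 genes in the test of the cultivar by drought interaction (edgeR, adjusted p under 0.05), and 3724 had an unadjusted p under 0.05. For 624 of the 1095 genes (57%), the cultivar whose response lay farthest from the median cultivar was WRC09, where control and drought plants differed in cultivar-specific genes, above it in 318 and below it in 306. WRC02 followed with 9.41% of the genes, in all but 1 of them below the median, and WRC24 with 88. Of the 1095 genes, 1000 were called in at least 1 cultivar and 765 in WRC09. In 708 genes the fitted fold was at least 2 upward in at least 1 cultivar and downward in another. These are extremes of 40 fitted values, WRC09 included, and not calls, and their share over all tested genes was not computed. Genes called higher in one cultivar and lower in another numbered 148 among all tested genes, and 31 without WRC09. Of the 375 genes called over the 40 cultivars, 68 were among the 1095. When WRC09 was left out, 134 genes passed, all of them among the 1095, and 65 when WRC24 was left out as well. Without one of the replicate numbers the count was 252, 767 or 335, the first without replicate 1.

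Dro1-NIL differed from IR64 by 37 genes in control leaves, 28 higher and 9 lower, and most of the difference lay in 1 stretch of chromosome 9. Of the 42 genes with an adjusted p under 0.05 at any fold, 26 were on chromosome 9 (61.9%), which holds 5.58% of the tested genes (Fisher's exact test, two-sided, p = 1.5e-22, odds ratio 28). All 26 lay from LOC_Os09g26400 to LOC_Os09g32620, a stretch with 340 of the 1578 tested genes of the chromosome, or 21.5%. These end points were chosen after their values were seen.

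Within this stretch some genes had reads in one line only. LOC_Os09g26530 had 0 reads in the 3 control libraries of IR64, against 17 ± 2.14 CPM in Dro1-NIL and 9.17 ± 0.565 CPM in KP (SD, n = 3). Against the limit of 3 reads over the IR64 libraries, it was at least 268-fold higher in Dro1-NIL. LOC_Os09g26510 showed the opposite, with 0.95 ± 0.324 CPM in IR64 (47 reads) and 0 reads in Dro1-NIL and in KP. LOC_Os09g27900, chosen after its values were seen, stood at 54.4 ± 4.74 CPM in IR64, 11.7 ± 3.16 in Dro1-NIL and 12 ± 0.958 in KP. LOC_Os09g27920, chosen in the same way, stood at 0.645 ± 0.333, 7.96 ± 2.32 and 8.91 ± 3.03 CPM.

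In this stretch Dro1-NIL lay nearer to KP than to IR64. In all 26 genes the difference of Dro1-NIL from IR64 in control leaves had the same sign as that of KP from IR64 in drought leaves, a set of libraries not used to choose the genes (exact binomial test, two-sided, p = 3e-08). The control level of Dro1-NIL also lay nearer to the drought level of KP than to that of IR64 in 26 of 26. Both differences were measured from IR64, and the 26 genes are neighbours, so an even split over independent genes is not the right background. No other cultivar was compared, so these counts do not tell KP from other lines that differ from IR64. Of the 16 genes on other chromosomes, 13 had the same sign (exact binomial p = 0.021) and 9 were nearer to KP (exact binomial p = 0.80). Among these, LOC_Os03g20140 on chromosome 3 had 0 reads in IR64 and 33.2 ± 2.99 CPM in Dro1-NIL, at least 522-fold higher, and 29.8 ± 4.58 CPM in KP. LOC_Os11g25210 on chromosome 11 had 3.05 ± 1.12 CPM in IR64, 1 read over the Dro1-NIL libraries and 0 in KP. In drought leaves 28 genes differed between the lines, 18 higher in Dro1-NIL, and 23 of them were also called in control leaves in the same direction. Leaving out one of the replicate numbers left 19 to 23 of the 37 in number, with 2 libraries a side.

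**Figure D4:**
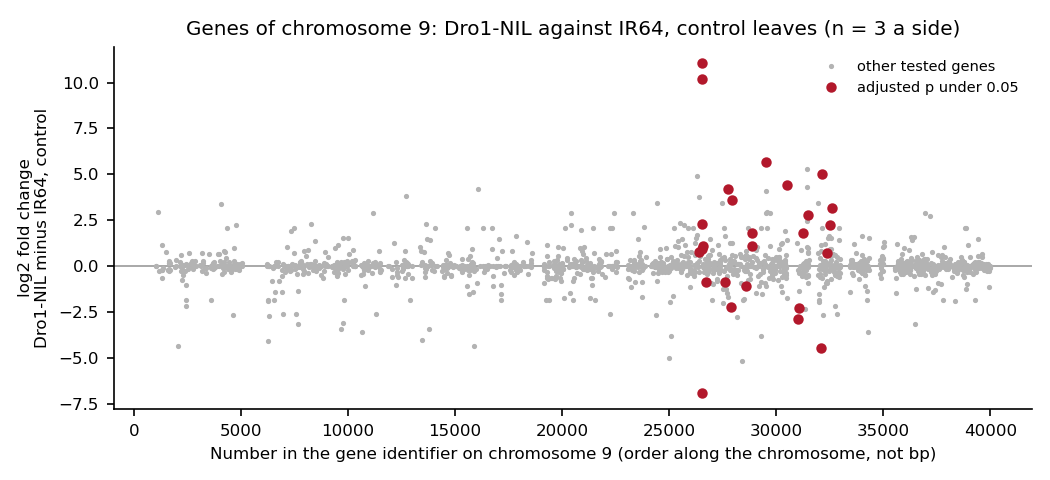
Log2 fold change of Dro1-NIL against IR64 in control leaves (n = 3 a side) for the 1578 tested genes of chromosome 9, ordered by the number in the gene identifier, which follows the chromosome but is not a distance. The 26 genes with an adjusted p under 0.05 (large points) all lie in the stretch from LOC_Os09g26400 to LOC_Os09g32620; fitted values beyond 6 in size belong to genes without a read in one line and have no upper bound.

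The drought responses of Dro1-NIL and IR64 differed at 1 gene. An unadjusted p under 0.05 was found for 399 genes, where evenly spread p values would give 1415. The p values of this comparison thus ran large, so the low count does not show that the responses are alike. The gene that passed, LOC_Os02g44530 on chromosome 2, is named because no other did, after its values were seen. It stood at 54.6 CPM in IR64 drought replicate 1 and at or below 1.27 CPM in each of the other libraries of both lines. In edgeR, 0 genes passed with replicate number as a block or without any one of the replicate numbers. DESeq2 was not run for this comparison.

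A score of 10 genes, chosen each time without the cultivar to be assigned, placed 84.1% of the libraries in their treatment (201 correct, Wilson interval 78.9 to 88.2%). The interval takes libraries as independent, whereas those of a cultivar shared a gene choice and part of their score level, so it can be too narrow. The share was 85.8% for control and 82.4% for drought libraries, and 82.3%, 83.8% and 86.3% for replicates numbered 1, 2 and 3. With treatment labels swapped within cultivars, the highest of 100 repeats was 57.7% (permutation p = 0.0099, the smallest that 100 swaps allow). Scores of 10 genes drawn at random among the tested genes reached a median of 63.6%, from 56.1 to 69.5%. Every library was assigned correctly in 18 of 40 cultivars. With 1 gene the share was 75.7%, and with 50 genes it was 85.8%.

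No gene entered the score in all 40 rounds, and 5 entered in 39. When WRC47 drought replicate 3, the library of 362 reads, was left out, 7 genes entered in every round, 0 of the former 5 among them, and 89.9% of libraries were assigned correctly.

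**Figure D5:**
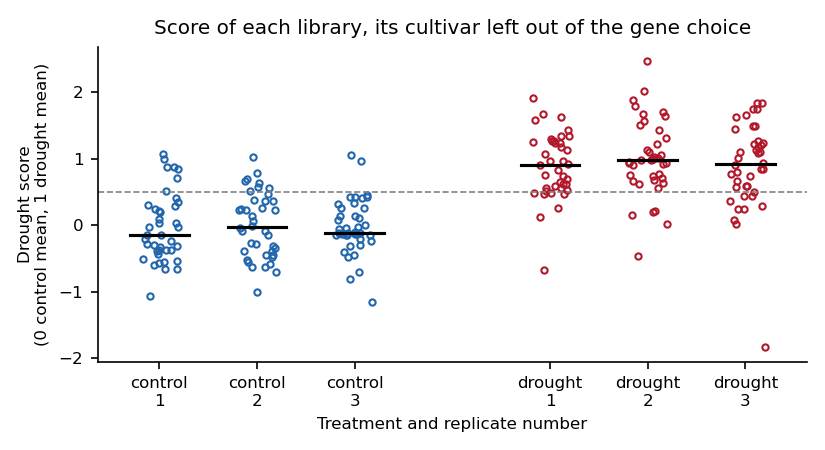
Drought score of each library from the round in which its cultivar was left out, by treatment and replicate number; circles are libraries, bars are medians, and the dashed line is the midpoint between the control mean (0) and the drought mean (1) of the training cultivars. Of the control libraries 85.8% lie below the midpoint and of the drought libraries 82.4% above it.

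The level of the score differed among cultivars within a treatment. WRC24 had the widest separation, from -1.07 ± 0.07 in control to 1.69 ± 0.86 in drought (SD, n = 3), and WRC44 stood at 0.83 ± 0.32 and 0.90 ± 1.02. Among drought libraries, 39% of the variance of the score lay among cultivars (permutation p = 3e-05), and among control libraries 49.5% (permutation p = 1e-05, the smallest that 100000 permutations allow). Each cultivar was scored in its own round, with its own choice of genes and its own scale. The permutations exchanged finished scores, so they do not separate cultivars from rounds. The shares moved with the libraries included. Without WRC47 drought replicate 3 they were 16.7% (permutation p = 0.041) and 12.7% (permutation p = 0.087), whereas without replicate number 3, which also leaves out that library, they were 41.1% (permutation p = 0.0071) and 29.4% (permutation p = 0.038). Without replicate number 1 they were 1.94% (permutation p = 0.39) and 42.3% (permutation p = 0.0032), and without number 2 they were 10.3% (permutation p = 0.18) and 37.9% (permutation p = 0.0072). With only libraries of at least 1 M reads the shares were 8.09% (permutation p = 0.20) and 7.80% (permutation p = 0.20).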

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

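The counts without one replicate number were fixed before the data were examined, and the other tests in this part were chosen after the result was seen, except that the bounds for the interaction count without WRC09 and for the share of genes without reads in another cultivar were set before those values were seen.

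The 1095 genes of the cultivar by drought interaction stood out because the test of the difference between cultivars itself passed. On the 4043 genes examined for other labellings within cultivars, the real labels gave 165 genes and 2 of 40 labellings gave as many. The highest other gave 252 and the median of the others was 11. This does not settle whether chance accounts for it, because exchanging labels can carry the shared drought response into this test, by an amount not measured. The 3 other labellings that kept the WRC09 libraries apart by treatment gave 130 to 252 genes and the rest at most 87, so these counts follow how WRC09 was divided. When WRC09 was left out, the count over all tested genes fell from 1095 to 134, under the bound of 300 set for WRC09 alone as the source of most of it.

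WRC09 and WRC24 had the most called genes, which depth of the drought libraries (Spearman correlation with called genes over the cultivars -0.143) does not account for; without any one replicate number WRC09 still had the most, with at least 1856, but WRC24 fell to 379 and rank 5 without number 2, so the part of that number stays open. In WRC24, where 97.6% of the called genes moved with the mean of the other cultivars, the pattern is consistent with a larger response in the shared direction, whereas in WRC09 that share was 72.6%, so such a response is not the whole of it. For WRC09 a candidate explanation is that control and drought plants were of different genotypes: over genes chosen in other cultivars their profiles correlated at only 0.451. Drought acting on genes that all the other cultivars express is argued against for the 110 genes read in only one treatment, as 95.5% of them had no read in at least 1 other cultivar. If so, how 2 genotypes came under 1 label, which of them is WRC09, and how much of the 3141 genes is a response to drought stay open, since the 2 sets of plants coincide with the treatments.

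Single cultivars reached high counts under other labellings too. In WRC100, where the real labels gave 2 genes, another labelling gave 1779, more than the 1503 of WRC24, so a high count in 1 cultivar with 3 libraries a side is not by itself a sign of drought; 40 labellings hold too few splits of any 1 cultivar to test its count.

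The difference of the drought responses of Dro1-NIL and IR64 stood out because its own test passed at 1 gene; with replicate number as a block 0 genes passed. Of 40 labellings of the libraries of both lines within treatments, 27 gave at least 1 gene and the highest of the others gave 78. These counts do not settle whether chance accounts for the 1 gene, because the other labellings carry the difference between the lines into the test: the count rose with the amount carried (Spearman correlation 0.821), and the 22 other labellings that carried least gave at most 4 genes.

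Among the remaining counts, the 375 genes over all cultivars were examined on 4043 genes, of which 54 were called; of 40 labellings within cultivars 1, the real one, gave as many, the highest other gave 1, and chance can be excluded. For the median of 11.5 genes per cultivar, 1 of 40 labellings gave as high a value, the highest other was 2, and chance can be excluded. These labellings do not separate drought from other differences between the control and drought library series. For the 37 genes between Dro1-NIL and IR64, 1 of 10 splits gave as many and the highest other gave 1, but 10 splits are too few for a share under 0.05. Other values argue against chance for these genes as a set. Of the 42 genes at any fold, 61.9% were on chromosome 9, against 5.58% of the tested genes. In separate drought libraries, 23 of the 28 genes called were also called in control leaves in the same direction.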

How the results depend on the processing

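The alternatives on libraries of at least 1 M reads, on WRC47 drought replicate 3, on the 3 libraries between 2 cultivars and on cultivars left out were chosen after seeing the data.

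Over the 40 cultivars the count of 375 became 12567 with no fold minimum, 184 with a mean of at least 1 CPM, where fewer genes were tested, and 579 with replicate number 3 alone; the cause of the last was not tested. The other alternatives gave 326 to 473, among them 368 to 459 without one replicate number or without WRC47 drought replicate 3. The median of 11.5 genes per cultivar became 4.5 with no filter on low counts, 0 to 1 without one replicate number, where 2 libraries a side remained, 8 with WRC09 left out and 9 without WRC47 drought replicate 3, and, with each cultivar fitted alone, 0.5 in edgeR and 111.5 in DESeq2; the cause was not tested. Single cultivars moved further, such as WRC32 from 18 to 1375 with RLE size factors, KP from 453 to between 13 and 63 without one replicate number, WRC09 to between 1856 and 2538 and WRC24 to between 379 and 1259. The interaction count of 1095 became 134 with WRC09 left out and 65 with WRC09 and WRC24 left out, so most of it rested on WRC09; it was 252 to 767 without one replicate number, 1052 without WRC47 drought replicate 3 and 964 to 1155 otherwise, apart from the value below. The 37 genes between Dro1-NIL and IR64 became 19 to 23 without one replicate number, 36 without WRC47 drought replicate 3 and 34 to 38 otherwise. The 1 gene of their difference of responses became 0 without any one replicate number, and 1 in the other alternatives but the one below.

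The prediction, at 84.1%, became 75.7% with 1 gene, 63.6% with genes drawn at random, 80.5 to 94.3% without one replicate number, 88.9% with libraries of at least 1 M reads and 89.9% without WRC47 drought replicate 3. The share of the score's variance among cultivars, at 39%, became 1.94% without replicate number 1, 10.3% without number 2 and 8.09% with libraries of at least 1 M reads, where the permutation test no longer passed, and 41.1% without number 3, where it passed; it fell to 16.7% without WRC47 drought replicate 3 and passed at p = 0.041. The 4 genes named over the 40 cultivars kept their call in all 72 alternatives. They had been chosen for large changes in these same libraries. The alternative with no fold minimum repeats the main fit, so its outcome was fixed. The gene lists were not run, nor were their alternatives, because no identifier matched.

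Replicate numbers did not pair the libraries: deviations of control and drought libraries of the same cultivar and number correlated at 0.0464 in the mean, against -0.0234 for different numbers. With replicate number as a block the counts were 375 over the cultivars, 12 for the median cultivar, 1244 for the interaction, 38 for Dro1-NIL against IR64 and 0 for their difference of responses. With each pair of libraries of one cultivar and number as a block, 436 genes passed over the cultivars and the median cultivar had 1.5. WRC13 and WRC28, each with 1 drought library under 1 M reads, had 0 called genes with and without it, and WRC02, with another, had 442 and 340; what depth limits in single cultivars was not separated further.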

Other observations

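All tests in this part were chosen after the result was seen.

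Genes called over the 40 cultivars lay next to each other more often than shuffled genes, although most had no such neighbour. Of the 375 called genes, 42 lay directly beside another called gene of the same direction in the order of tested identifiers, against 5.04 on average and at most 23 in 10000 shuffles (permutation p = 0.0001, the smallest they can give). Random placement among the tested genes is not compatible with this. The shuffles do not show why neighbours were called together.

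By the slope, a measure chosen after the data were seen, cultivars differed in the strength of the shared drought response. Of the variance of the slopes between libraries of the same replicate number, 38.2% lay among cultivars (permutation p = 0.0001, the smallest that 10000 shuffles can give), so chance is excluded as the whole of it; with WRC09 left out it was 36.7% (permutation p = 0.0003). Over the 40 cultivars the slope went with the log10 of called genes at r = 0.534 (permutation p = 0.0006, adjusted p = 0.0024 over 4 relations) and rho = 0.388 (permutation p = 0.016, adjusted p = 0.064). Without the 2 cultivars farthest from the median slope, r was 0.356. Slope and mean drought depth had r = -0.00914 (permutation p = 0.96) and rho = -0.0193 (permutation p = 0.90). The slopes left out the shallow libraries. The drought score, a measure fixed before the data were examined, did not bear out a difference among cultivars without such libraries. Among drought libraries of at least 1 M reads 8.09% of its variance lay among cultivars (permutation p = 0.20), against 39% among all drought libraries (permutation p = 3e-05).

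Responses of different cultivars correlated to varying degrees. Over 780 pairs of cultivars the correlation of responses across 14605 genes ranged from -0.389 to 0.779, with a median of 0.353 and 714 above 0. The near-isogenic Dro1-NIL and IR64 reached 0.618, rank 70. Differences between libraries of single replicate numbers correlated at a median of 0.277 for 2 numbers of the same cultivar and 0.167 for different cultivars, a difference that was not tested. The hypothesis that cultivars with similar control profiles respond alike found little in its favour, with a Mantel correlation of 0.049 (permutation p = 0.068) and rho = 0.0255 (permutation p = 0.50). Since even replicate numbers of the same cultivar correlated at a median of only 0.277, a relation of this kind could have been missed.

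Genes without a read differed between cultivars; counts alone do not show whether such a gene is absent, silent or has reads that were not placed on the reference. Of 16873 genes with at least 5 CPM in every library of at least 1 cultivar, 1586 had 0 reads in all libraries of at least 1 other. The number of such genes without a read ran from 298 in Koshihikari and in WRC01, the Nipponbare accession whose genome is the reference, to 557 in WRC13. The shallow libraries and the 3 libraries between 2 cultivars were left out of these counts.

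The 3 libraries midway between 2 cultivars joined neighbours in the collection's numbering, WRC16 with WRC15 in a pair of libraries and WRC35 with WRC36. A whole library under a wrong label is excluded, since the highest median position was 53.2% of the way to the other cultivar. A plant of a selfed later generation of a cross is excluded too, as at most 2.16% of genes lay near an end, against at least 68.4% in the other libraries of these cultivars. A first-generation hybrid plant and an equal mixture of 2 plants or RNAs cannot be told apart: both give this position on every chromosome (chromosome medians 38 to 67.1%), and the correlation of gene positions between the 2 WRC16 libraries, 0.126, does not decide. No biological explanation from the design was tested.

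The stretch of chromosome 9 in which Dro1-NIL differs from IR64 holds 61.9% of the genes between the lines, which unequal library depth, acting on all chromosomes alike, would not give. With 26 of 26 genes nearer to KP than to IR64, and no other cultivar compared, a segment shared with KP is a candidate explanation. It is what the name of the line leads one to look for. Of these genes, 4 had no read in the control libraries of one line. Whether such genes are absent, silent or too different from the reference for their reads to be placed cannot be told apart from counts alone. The genes are therefore not shown to differ in transcription, and whether any has a part in rooting or drought was not examined.

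Within groups of libraries with the same treatment and replicate number, 1 of 24 tests found a trend with library number. The fourth component of the differences between replicates, with 5.36% of their variance, followed library number in drought replicates numbered 1, with a Spearman correlation of 0.609 in size (permutation, adjusted p = 0.0048).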
